A study of Tricholoma matsutake and Tricholoma matsutake
Pinus densiflora and Pinus densiflora with 12 samples.

How the data were processed

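The samples were RNA-seq libraries of 4 materials with 3 libraries each, 12 in total. Mycorrhiza was *Tricholoma matsutake* strain IS01 grown with *Pinus densiflora*. Mycelia were the same strain on agar, fruiting bodies were collected in the wild, and pine root was grown without the fungus. RNA of mycorrhiza and pine root was extracted with CTAB, and RNA of mycelia and fruiting bodies with a kit. Extraction method and material therefore cannot be told apart in the comparisons of mycorrhiza with mycelia and with fruiting bodies. Mycorrhiza grew at 23 °C in the light and mycelia at 25 °C in the dark, so temperature and light cannot be told apart from the material either. Fruiting bodies came from the wild and the other fungal materials from culture of strain IS01. Growth conditions and fungal genotype therefore cannot be told apart from the stage in comparisons with fruiting bodies. The label of the pine root samples also names strain IS01. The aligner and the genome builds were not given in the sources used here, although the fungal gene models carry identifiers of the JGI Trima3 set.

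Per the file headers, the fungal values were RPKM (reads scaled to gene length and to all mapped reads) computed by the authors. The pine tables held counts and RPKM per contig as deposited. The mycorrhiza reads in the pine tables were, per the file headers, those that had not mapped to the fungus. The deposited tables also held a p-value, an FDR-corrected p-value and a fold change computed by the authors. These were used only where the text names the authors' deposited table. A column of values was given to a library only where its name matched the labels of that library and of no other, which left 24 columns not used here, 18 in the fungal table and 6 in the pine table. The pine count columns named the group without a replicate number and are called columns A, B and C of each group. The fungal files listed 22885 gene models, of which 8854 were at 0 in every library and 14031 had a value. The pine files listed 47191 contigs with values and 1 contig without. A description was given for 9093 fungal genes, and it named a protein or domain for 8774. The files pair contigs with no descriptions, so the 28 lists prepared for pine were not analysed here.

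Reads per fungal gene were recovered from the RPKM as the smallest whole number of reads per library that gave back the deposited values, trying gene lengths up to 40000 bases. Whole reads were found for 100% of the genes with values in at least 6 libraries, and they gave back 100% of the values within 1e-6. In a simulation of 5999 genes every read count came back for 99.9% of genes, and the mapped reads of all 9 libraries were exact. Of the recovered fungal lengths 56.5% were divisible by 3, against 33.1% for pine contigs. These recovered reads served for depth, for counting intervals and for alternatives, not for the reported fungal test.

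A count test had been planned where counts were deposited, and a test of log values otherwise. Fungal genes were therefore tested with limma (trend) on log2(RPKM + 1) in 1 fit of 9 libraries, keeping genes with RPKM of at least 1 in at least 3 libraries. On this scale fold changes of weakly expressed genes are understated. Folds quoted as such are ratios of mean RPKM, and log2 changes are those of the fit. Pine contigs were tested with edgeR quasi-likelihood on the deposited counts of 6 libraries after filterByExpr and TMM scaling. The adjusted p threshold was 0.05 (Benjamini-Hochberg) in every test. Gene lists were tested with camera at the preset inter-gene correlation of 0.01 and again with an estimated correlation, for lists with at least 5 tested genes. R 4.3.3, limma 3.58.1, edgeR 4.0.16, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

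The comparisons, 25 fungal lists matched on words of the descriptions (which also take in some genes of other function), the test, the alternatives and the rule for named genes were fixed before the data were examined. The rule named, per comparison, the 8 genes with the largest rise and the 8 with the largest fall among those with an adjusted p under the threshold, a mean RPKM of at least 10 in the higher group, libraries of both groups that did not overlap and an informative description. It also named up to 3 called members per list and direction with the smallest adjusted p, and the 8 genes with the largest smaller rise among those higher in mycorrhiza than in both other materials. Other genes in the text, namely those listed at 0 and their copies, were chosen after their values were seen. A further list of protein families taken to be near-identical in plants and fungi, judged from the descriptions without any sequence, was also chosen after the values were seen, as were the centred, rescaled and recovered-read alternatives. Genes at 0 are given as listed values. Where a group held 1 to 3 reads over its libraries, the ratio is that of the reads pooled over each group and scaled to its mapped reads, given with its 95% counting interval. Intervals cover counting error only, since reads are not independent molecules.

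Known changes were planted in simulated libraries at these depths to measure what the tests could find. They were planted in 66 or 67 genes per fold size. Only fungal genes with a mean RPKM of at least 10 over the fungal materials, or contigs with a mean of at least 100 reads, were used. The rates therefore do not hold for genes read more weakly. For mycorrhiza against mycelia, limma found 25.4% of 2-fold changes, 97.0% of 4-fold changes and 98.5% of 8-fold changes. Of the 11357 genes in this test, 22 unchanged genes were called, 13.0% of the calls. On pine counts edgeR found 10.4%, 83.6% and 100% of the 2-, 4- and 8-fold changes, with 11 unchanged contigs called. DESeq2 found 41.8%, 98.5% and 100% there, with 119 unchanged contigs called, 42.7% of its calls.

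The alternatives were another pseudocount (0.1), no filter on low values, a log2 change of at least 1, each library left out in turn, replicate number as a block, and only the libraries of the compared groups. The fungal tests were also rerun on RPKM centred on the median gene of each library, on recovered reads with edgeR (TMM or DESeq2 size factors) and DESeq2, on thinned reads, and without the near-identical families. The pine test was also run with DESeq2, with DESeq2 size factors in edgeR, on thinned counts, on reads recovered from the RPKM, and without contigs under 3 reads in pine root. Nothing in the labels says that the libraries of a group came from separate cultures or separate wild collections. The p-values therefore measure only the spread between these samples, part of which may be technical.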

Results

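Transcripts were counted by RNA-seq in 4 materials with 3 libraries each. Mycorrhiza was the ectomycorrhizal fungus *Tricholoma matsutake*, strain IS01, grown in bottles for 6 months with a seedling of its host *Pinus densiflora*, after 1 month of culture alone. The fungus was also sampled as mycelia of the same strain after 6 months on agar and as fruiting bodies collected in the wild. Pine root was cultured for 6 months without the fungus. Fungal gene models were read in mycorrhiza, mycelia and fruiting bodies, and pine contigs in mycorrhiza and pine root. Reads in fungal genes numbered 621983, 290541 and 710850 in mycorrhiza 1, 2 and 3. They numbered 26548862, 32470528 and 20321221 in mycelia, and 26802226, 10124305 and 11513813 in fruiting bodies. Fungal reads were 2.19%, 2.46% and 3.26% of the fungal and pine reads of mycorrhiza 1, 2 and 3. One read in a gene of 1 kilobase stood for an RPKM of 1.28, 2.70 and 1.10 in the mycorrhiza libraries, and for 0.0254 to 0.0388 in mycelia. Pine counts totalled 16131881, 16759040 and 27143560 in columns A, B and C of pine root, and 27887042, 11561351 and 21211413 in those of mycorrhiza. Values of fungal genes are mean RPKM ± SD with n = 3 libraries per group throughout.

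**Figure D1:**
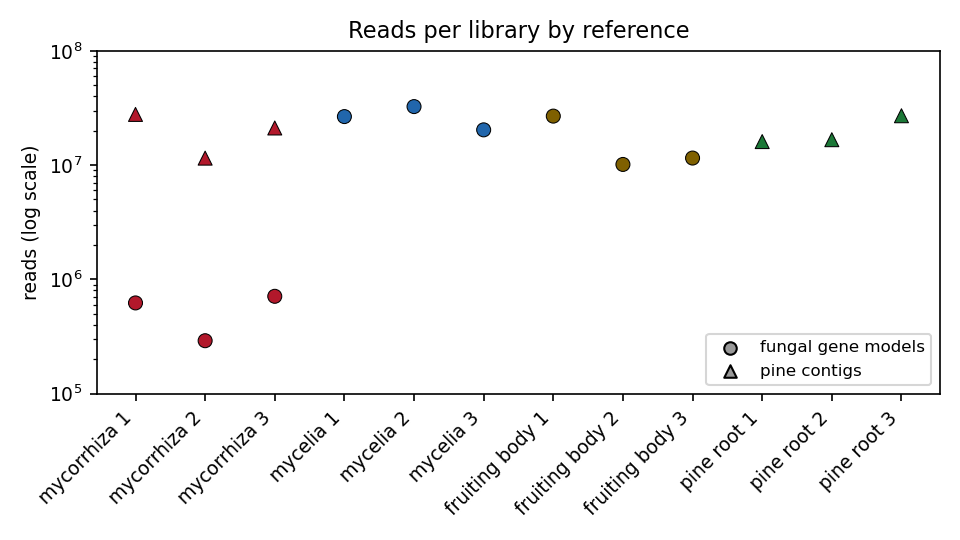
Reads per library on a log axis, with circles for fungal gene models and triangles for pine contigs. The mycorrhiza libraries held 290541 to 710850 fungal reads, against 10124305 to 32470528 in the fruiting body and mycelia libraries.

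The comparison of mycorrhiza with mycelia asked which fungal genes differ between growth on the host root and growth alone. Sugar transporter 1383836 was at 234 ± 16.7 in mycorrhiza and 2.74 ± 0.67 in mycelia, 85.4-fold higher (log2 change 5.99, SE 0.40; limma adjusted p = 6.01e-06). Its relatives 1384198, at 95.8 ± 26.9 and 3.62 ± 0.20, and 1412049, at 276 ± 55.1 and 35.1 ± 4.65, were 26.5-fold and 7.87-fold higher (limma adjusted p = 5.68e-06 and 4.25e-06). Sugar transporters carry hexoses across the fungal membrane, where carbon from a host enters the cell. Fungal mating-type pheromone 1384894 was at 6525 ± 1663 in mycorrhiza and 32.9 ± 17.3 in mycelia, a 199-fold difference (limma adjusted p = 1.55e-06). Another 2 pheromone genes, 1384913 at 4459 ± 3187 and 1399594 at 383 ± 194, were 60.1-fold and 38.9-fold higher, the former 39.1-fold without mycorrhiza 2. ABC transporter 1457957 fell from 300 ± 6.66 in mycelia to 5.07 ± 0.81 in mycorrhiza, 59.2-fold (log2 change -5.64, SE 0.23; limma adjusted p = 5.13e-07).

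Of 11504 fungal genes tested, limma called 1407 higher and 4992 lower in mycorrhiza than in mycelia, 22.0% of the calls being higher. The median gene was at a log2 change of -0.60. After each library was centred on its median gene, 2952 were higher and 2249 lower, and with edgeR on recovered reads 2556 were higher and 2465 lower with TMM scaling and 2582 and 2439 with DESeq2 size factors. DESeq2 itself called 2938 higher and 2427 lower. With TMM 1380 of the 1407 higher calls remained and 2465 of the 4992 lower calls. Centring shifts all genes of a library alike, and both it and TMM moved mycorrhiza upward here, which favours higher calls over lower ones. Of the lower calls 2249 remained after centring. The lower genes given with values for this comparison were called lower after centring too. In the authors' deposited table all 1407 had a fold change above 1, and of the 4992 lower genes 4929 were lower and 63 higher. At its unadjusted p under 0.05 the authors' deposited table itself held 3301 genes higher and 2731 lower in mycorrhiza, the opposite balance. In groups without any change simulated at these depths, limma called 0.2 genes higher and 5.45 lower on average over 20 draws, with at most 13 lower.

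Among sugar transporters 13 of 41 tested genes were higher and 8 lower, with the same counts adjusted over the list alone and 16 and 2 after centring. The set was higher relative to other genes (camera adjusted p = 0.00148), but adjusted p = 0.383 with an estimated correlation. Its median log2 change was -0.07 and its mean 0.58. The 8 members that fell included some of other function, such as chloride channel 1433354, which went from 33.3 ± 5.23 to 13.2 ± 1.84, and UDP-galactose transporter 1246209 was 3.51-fold lower.

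Enzymes that degrade plant cell walls, which fungi secrete to open or digest plant tissue, were called in both directions. Of 40 tested genes 9 were higher and 7 lower, the same adjusted over the list alone, and 19 and 2 after centring. The GH61 gene 1360717 was at 123 ± 8.54 in mycorrhiza and 27.4 ± 4.52 in mycelia, 4.49-fold higher (limma adjusted p = 7.41e-06). The GH7 gene 1246307 was at 83.2 ± 4.91 against 33.3 ± 5.74. Besides the enzymes the list held the cerato-platanin 1363920, which was 4.70-fold higher, at 324 ± 79.7 against 68.9 ± 31.1. The GH18 gene 1392237, a family that acts on chitin rather than on plant walls, fell 4.51-fold, and the GH5 gene 1365477 fell 3.24-fold. The set passed relative to other genes (camera adjusted p = 0.0129), with adjusted p = 0.322 with an estimated correlation. Its median log2 change was -0.01 and its mean 0.09.

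Hydrophobins, small secreted proteins that coat hyphae, held 2 higher and 1 lower of 8 tested genes, the same adjusted over the list alone and 3 and 1 after centring. Hydrophobin 1386086 was at 227 ± 142 in mycorrhiza and 11.1 ± 3.71 in mycelia, and 1291850 at 517 ± 377 and 49.2 ± 8.27 (limma adjusted p = 0.000243 and 0.000729). Without mycorrhiza 1 the mean of 1291850 was 312, 6.34-fold above mycelia. Hydrophobin 1383622 was lower, 2.62 ± 3.32 against 16.8 ± 3.53, with a ratio of pooled reads of 9.53 and a counting interval of 3.25 to 46.2. By mean RPKM it was 22.3-fold lower without mycorrhiza 2 and 4.27-fold without mycorrhiza 3, but both folds rest on at most 3 mycorrhiza reads. The set passed upward (camera adjusted p = 0.0421), with adjusted p = 0.328 with an estimated correlation.

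Redox and detoxification genes, which handle reactive oxygen and reduced substrates, gave 38 higher and 31 lower of 135, and 38 and 30 adjusted over the list alone. After centring 68 were higher and 8 lower. Aldo/keto reductase 1405810 was at 180 ± 20.1 in mycorrhiza and 17.96 ± 5.99 in mycelia, and 1394106 at 216 ± 14.5 and 44.9 ± 2.37. A thiol-specific antioxidant protein, 729603, was 6.31-fold higher, while thioredoxin-type gene 1385872 fell from 195 ± 19.2 to 49.4 ± 1.91. The set was higher relative to other genes (camera adjusted p = 6.94e-05), with adjusted p = 0.322 with an estimated correlation.

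Ribosomal proteins, which build the translation machinery, gave 71 higher and 34 lower of 182, and 71 and 35 adjusted over the list alone. After centring 125 were higher and 15 lower. Ribosomal protein S6 gene 1298991 was at 252 ± 16.2 in mycorrhiza, 1.20 ± 1.82 in mycelia and 251 ± 46.4 in fruiting bodies. Mycelia 1 alone held 3.29 of it, and without that library the mycelia mean was 0.155. L13 gene 1388549, of the organelle type, was 2.39-fold lower in mycorrhiza than in mycelia, at 40.8 ± 2.12 against 97.3 ± 1.37 (limma adjusted p = 5.43e-05). The set passed upward (camera adjusted p = 1.42e-10), with adjusted p = 0.390 with an estimated correlation. Of all genes on this list, tested or not, 3 were also among the near-identical families.

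Transcription factors, which set which genes are read, were lower as a set relative to other genes (camera adjusted p = 0.00148), with adjusted p = 0.322 with an estimated correlation. Of 514 genes 45 were higher and 325 lower, 45 and 334 adjusted over the list alone, 75 and 176 after centring and 67 and 205 with TMM. The NF-X1 type gene 1325358 fell from 207 ± 37.7 in mycelia to 32.6 ± 4.97, and the HMG-I/Y gene 406631 from 48.0 ± 3.24 to 2.46 ± 0.92 (limma adjusted p = 5.68e-06 and 7.33e-06). The MYND zinc finger gene 1396008 rose 14.2-fold, at 280 ± 26.2 against 19.7 ± 5.98. The list also took in a glyoxal oxidase, 1445291, and a Tim10-type mitochondrial import protein, 1186349, which are not transcription factors and were 4.42-fold and 3.56-fold higher.

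Other members of lists that did not pass as sets were called singly. Ferric reductase 1356177 was at 203 ± 126 in mycorrhiza and 4.35 ± 0.70 in mycelia, and GDSL lipase 1458502 at 576 ± 251 and 20.3 ± 2.12. Glutamine synthetase 1421031, which fixes ammonium, was 4.36-fold higher, whereas the nitrite reductase-type gene 1408096 fell from 132 ± 19.3 to 7.21 ± 1.12 (limma adjusted p = 1.39e-06). Chitinase 1375615 was 14.3-fold higher and chitinase 506547 5.53-fold lower. Of 48 glycolysis and TCA cycle genes 6 were higher and 10 lower, 6 and 9 adjusted over the list alone, and the balance turned to 20 and 2 after centring. Of 57 nitrogen and amino acid genes 7 were higher and 19 lower, 7 and 18 adjusted over the list alone, and the balance turned to 21 and 7 after centring. Of 54 genes on a list of plant-type transcripts, used as a marker of the other organism, 13 were higher and 16 lower (camera adjusted p = 0.101). For these plant-type transcripts the balance turned to 22 higher and 4 lower after centring and to 19 and 5 with TMM. The list does not mark pine reads by itself, since members such as the organelle-type L13 gene 1388549 and S18 gene 1456783, at 97.3 and 220, were well read in mycelia grown without pine.

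The 8 largest rises among described genes that met the naming rule were all in protein families taken, from their descriptions alone, to be near-identical in plants and fungi. Their level in fungal cells is uncertain, because no sequences were compared and pine reads among theirs were not ruled out. Polyubiquitin gene 1375997 took 15.1%, 13.6% and 11.01% of the fungal reads of mycorrhiza 1, 2 and 3, whereas the top gene of the other fungal libraries took 0.468% to 1.33%. The ubiquitin-L40 fusion gene 1292540 was at 16520 ± 3557 in mycorrhiza and 48.7 ± 8.78 in mycelia, a ratio of 339. Actin gene 1380975 was at 420 ± 103 in mycorrhiza with 1 read in mycelia, a ratio of pooled reads of 16200 with a counting interval of 2880 to 641000. Histone H2B gene 1204762 was at 2905, 2145 and 1927 in the mycorrhiza libraries and listed at 0 in each library of mycelia and fruiting body. The 14-3-3 gene 1340759, at 1036, 921 and 796 in mycorrhiza, was also listed at 0 in each of those libraries. Of 62 tested members 35 were higher and 10 lower than in mycelia, and the members higher than in both other materials held 26.5%, 22.8% and 19.4% of the fungal reads of mycorrhiza 1, 2 and 3. When the families were left out and RPKM was rescaled, limma called 2067 genes higher and 3363 lower.

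At the other end, RNA polymerase subunit gene 1250091 was listed at 0 in each mycorrhiza library. It was at 75.4, 79.9 and 114 in mycelia and at 28.4, 25.4 and 26.3 in fruiting bodies. G protein alpha subunit gene 1381059 was also listed at 0 in each mycorrhiza library, against 37.7, 42.1 and 30.3 in mycelia and 112, 109 and 86.0 in fruiting bodies.

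The comparison of mycorrhiza with fruiting bodies asked which genes differ between the symbiotic and the reproductive stage of the fungus. Stage could not be told apart here from genotype or from growth in the wild or in culture. Aquaporin 1411595, a membrane channel for water and small solutes, was at 187 ± 35.6 in mycorrhiza and 0.80 ± 0.22 in fruiting bodies, 234-fold higher (log2 change 6.70; limma adjusted p = 3.88e-08). Cytochrome P450 gene 1410125 was at 114 ± 18.9 and 1.61 ± 0.07, and 1381062 at 172 ± 57.2 and 3.20 ± 0.82. Hydrophobin 1252927 was 83.1-fold lower in mycorrhiza, at 79.6 ± 65.2 against 6613 ± 2082 (limma adjusted p = 4.95e-05). Dyp-type peroxidase 1440330 was at 12.6 ± 12.1 in mycorrhiza and 983 ± 60.6 in fruiting bodies (limma adjusted p = 1.6e-05).

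Of the 11504 genes limma called 1847 higher and 4319 lower in mycorrhiza than in fruiting bodies, 29.95% of the calls being higher, and the median gene was at a log2 change of -0.41. Centred values gave 2876 higher and 2616 lower. TMM gave 2482 and 2813, and leaving out the near-identical families gave 2579 and 2949. With DESeq2 size factors in edgeR 49.3% of the calls were higher, and with DESeq2 52.5%. With TMM 1784 of the higher calls remained and 2811 of the 4319 lower calls, of which 2616 remained after centring. The genes given with values for this comparison kept their calls after centring, apart from 1464959 on the aquaporin list. Without mycorrhiza 1 the fold of 12 genes named as lower than in fruiting bodies moved by more than 1.5 times, and no other library moved as many. Hydrophobin 1252927 then became 150-fold lower, Dyp-type peroxidase 1440330 171-fold and cerato-platanin 234553, with 65.7 in mycorrhiza 1 and a mean of 6.73 in the others, 221-fold.

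Camera called 0 of the 25 lists in this comparison, where 8 had an unadjusted p under 0.05 and the smallest camera adjusted p was 0.089. Of 9 aquaporins 4 were higher and 2 lower, 4 and 3 adjusted over the list alone and 5 and 1 after centring, with 1451072 7.32-fold higher and 1391226 also higher (log2 change 3.48). Without fruiting body 3 the fold of 1451072 was 11.1. The 2 lower members of that list were no aquaporins by their main description, namely the protein phosphatase 300015, at 30.6 against 69.3, and the lipid-binding type gene 1464959, at 22.3 against 48.3, whose call ended after centring. Of 103 cytochrome P450 genes 33 were higher and 30 lower, and 45 and 27 after centring. Those lower included 1386291, at 20.0 ± 16.7 against 679 ± 143, and 1425460, at 37.6 ± 24.6 against 814 ± 181, whose means without mycorrhiza 1 were 10.5 and 23.5. Of 57 nitrogen and amino acid genes 13 were higher and 26 lower, 13 and 28 adjusted over the list alone and 16 and 18 after centring. Ammonium transporter 1377409 was 15.7-fold higher in mycorrhiza, at 195 ± 49.9 against 12.4 ± 3.75 (limma adjusted p = 7.37e-06). Of 129 heat shock genes 14 were higher and 63 lower, and 21 and 35 after centring. The Hsp9/12 gene 1403780 was at 63.5 ± 18.7 in mycorrhiza and at 18535, 13523 and 709 in the fruiting body libraries. Of 8 hydrophobins 2 were higher and 2 lower, the same after centring, with 1386086 20.9-fold and 1291850 4.21-fold higher than in fruiting bodies, the latter 2.54-fold without mycorrhiza 1. Ribosomal proteins gave 24 higher and 71 lower of 182, sugar transporters 10 and 14 of 41, and plant cell wall degrading enzymes 12 and 16 of 40. All 3 balances turned after centring, to 49 and 24, 13 and 9, and 15 and 11. Among those enzymes GH7 gene 1246307 was at 83.2 ± 4.91 in mycorrhiza and 9.13 ± 1.34 in fruiting bodies. Cerato-platanin 234553 was 56.5-fold lower. Catalase 1286238 was 24.7-fold higher and the glutathione S-transferase 1424940 61.5-fold lower, and redox genes were called 40 higher and 40 lower of 135, which became 58 and 26 after centring and 53 and 30 with TMM. The Doublesex-type transcription factor gene 1409882 was 143-fold higher, at 617 ± 193 against 4.31 ± 1.34, while transcription factors as a list gave 67 higher and 257 lower, and 107 and 167 after centring.

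The series asked for genes specific to mycorrhiza, which were taken here as those called the same way against both other fungal materials. Limma called 693 genes higher in mycorrhiza than in both, of which 376 had an informative description. Of these 376, 344 had a mean RPKM of at least 10 and mycorrhiza libraries that did not overlap those of either group. For any single comparison of 3 with 3 libraries, chance leaves no overlap in 10% of splits. Pheromone 1384894 was 407-fold above fruiting bodies as well (limma adjusted p = 5.23e-07). Sugar transporters 1383836, 1384198 and 1412049 were 65.1-fold, 21.4-fold and 20.2-fold above fruiting bodies. The concanavalin A-like gene 1406443 was at 809 ± 434 in mycorrhiza, 104.5 ± 57.03 in mycelia and 6.00 ± 1.06 in fruiting bodies. By list, and on RPKM without centring, genes higher in both comparisons included 21 of 135 redox genes, 7 of 41 sugar transporters and 7 of 40 plant cell wall degrading enzymes. They also included 14 of 182 ribosomal protein genes, 2 of 8 hydrophobins and 23 of 514 transcription factors. Of all 11504 tested genes 693 were higher in both, a larger share than that of transcription factors. Genes lower in both included 200 transcription factors, 15 redox genes, 26 ribosomal protein genes, 5 sugar transporters and 2 plant cell wall degrading enzymes, against 2797 of all 11504 tested genes.

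Genes lower in mycorrhiza than in both numbered 2797. Independent lists would share 226 higher and 1874 lower genes, and in simulated unchanged groups at these depths the overlap was 0 higher and 3.4 lower on average, with at most 12 lower. Both comparisons use the same 3 mycorrhiza libraries, so part of the excess may come from shared controls. With TMM 1177 genes were higher and 1282 lower in both, and after centring 1521 and 1081. With TMM 660 of the 693 higher genes and 1282 of the 2797 lower genes remained. Of the lower genes 1081 remained after centring and 1600 without the near-identical families, of which 26 were among the 693.

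**Figure D2:**
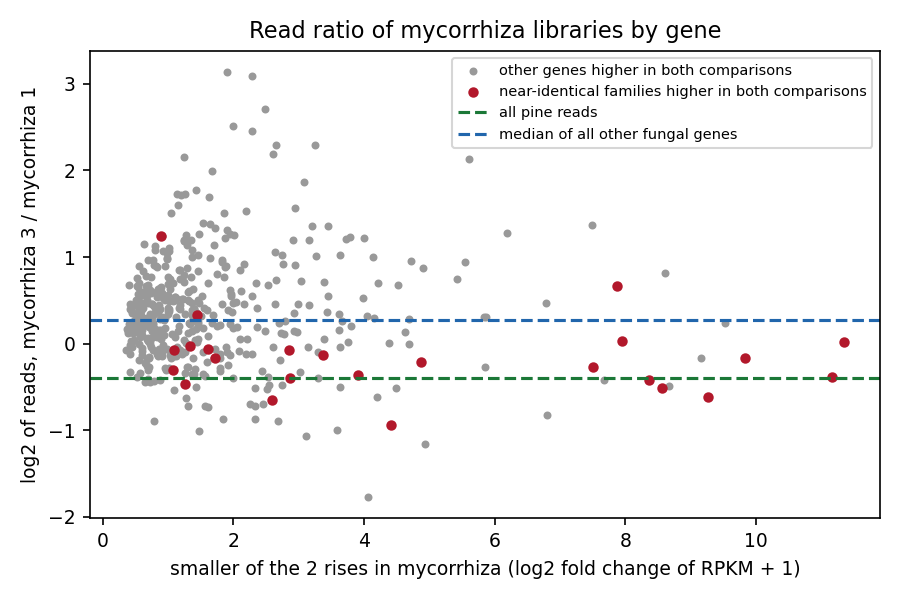
Log2 ratio of reads in mycorrhiza 3 over mycorrhiza 1 (y axis) against the smaller of the 2 rises in log2(RPKM + 1) (x axis), for genes higher in mycorrhiza than in both other materials with at least 20 reads in both libraries. Members of near-identical families (red) had a median of -0.19 and other genes (grey) of 0.32. The dashed lines mark all pine reads (green, -0.39) and the median of the tested fungal genes that were not higher in both (blue, 0.28).

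The comparison of fruiting bodies with mycelia gave the differences between the reproductive stage in the wild and growth of strain IS01 on agar. Here too stage could not be told apart from genotype or growth conditions. Hydrophobin 1252927 was at 6613 ± 2082 in fruiting bodies and 25.7 ± 18.3 in mycelia, 257-fold higher (log2 change 8.15, SE 0.67; limma adjusted p = 1.73e-05). Isoprenylcysteine methyltransferase genes 1413725 and 1449941, of an enzyme that modifies prenylated proteins such as pheromones, were 218-fold and 232-fold higher. Pheromone receptor gene 1374809 of the STE3 type was at 435 ± 145 against 9.09 ± 1.80 (limma adjusted p = 1.54e-05). A gene described as an N-acetylglucosaminyltransferase with WSC domains, 1331055, was 388-fold lower, at 7.29 ± 7.27 against 2827 ± 82.2. Alcohol dehydrogenase 1399257 fell from 3609 ± 891 to 19.1 ± 10.3.

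Limma called 2185 genes higher and 3322 lower in fruiting bodies than in mycelia, 39.7% of the calls being higher, with the median gene at a log2 change of -0.23. After centring 2729 were higher and 2543 lower, and with TMM 3377 and 3365. With TMM 2173 of the higher and 2982 of the lower calls remained, and 2543 of the lower calls after centring. The lower genes given with values for this comparison were called lower after centring too. Without mycelia 1 the fold of hydrophobin 1252927 was 420, and without fruiting body 2 that of 1331055 was 904.

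Ribosomal proteins were higher in fruiting bodies, with 91 genes higher and 16 lower of 182, and 95 and 18 adjusted over the list alone. The set passed (camera adjusted p = 1.73e-08), with adjusted p = 0.520 with an estimated correlation. L18 gene 1385859 was at 531 ± 67.6 against 180 ± 10.3, and after centring 99 members were higher and 12 lower. The other 24 lists did not pass camera, which gave 6 of the 25 an unadjusted p under 0.05. Histone genes H1 1397549 and H2A 1434264 were 52.2-fold and 61.7-fold higher in fruiting bodies, within a list of 205 DNA replication and histone genes of which 51 were higher and 49 lower, and 60 and 32 after centring. Of 9 aquaporins limma called 3 lower and the other 6 neither way, both before and after centring (camera adjusted p = 0.259), and 1411595 was 263-fold lower. Of 40 plant cell wall degrading enzymes 17 were higher and 11 lower, 18 and 11 adjusted over the list alone and 20 and 9 after centring. Endoglucanase-type gene 1444943 was 14.1-fold higher, at 1219 ± 142 against 86.7, and cerato-platanin 234553 233-fold higher. Of 103 cytochrome P450 genes 21 were higher and 38 lower, 22 and 38 adjusted over the list alone and 24 and 34 after centring, and 1381062 was 127-fold lower.

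The comparison of mycorrhiza with pine root asked which pine genes differ when the root carries the fungus. Contig_42852 had 4903, 2407 and 7069 reads in mycorrhiza columns A, B and C, and 2, 10 and 1 in those of pine root. Its mean was 240 ± 80.4 against 0.249 ± 0.292 CPM (counts scaled to the library total; SD, n = 3), 962-fold higher (log2 change 10.04, SE 0.65; edgeR adjusted p = 0.0199). Contig_39752 was 23.7-fold higher, at 17.1 ± 4.03 against 0.722 ± 0.192 (edgeR adjusted p = 0.0199). Contig_1235 fell from 558 ± 9.45 to 93.7 ± 5.75 CPM, 5.95-fold lower (edgeR adjusted p = 0.00188), and contig_3696 from 1073 ± 50.97 to 222 ± 38.8, 4.84-fold lower. The files pair these contigs with no descriptions. The log2 ratio of reads in mycorrhiza 3 over mycorrhiza 1 was 0.53 for contig_42852 and 0.26 for contig_39752, nearer to the median fungal gene at 0.28 than to all pine reads at -0.39. For mycorrhiza 2 over mycorrhiza 1 it was -1.03 and -1.12, against -0.85 for the median fungal gene and -1.27 for all pine reads. By this ratio contig_42852 was nearer to the median fungal gene but contig_39752 nearer to pine reads. Whether these contigs are of pine or of fungal origin was not tested.

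Of 37318 contigs tested, edgeR called 2 higher and 5 lower in mycorrhiza, the other 3 lower contigs being 2.81-fold to 4.01-fold lower. In all 7 the libraries of the groups did not overlap, which chance gives for 10% of contigs. At an unadjusted p under 0.05, 1659 contigs were higher and 1936 lower, and DESeq2 called 360 higher and 433 lower, all 7 among them. At an FDR-corrected p under 0.05 the authors' deposited table held 183 contigs that were higher and 442 that were lower, and all 7 were there in the same direction. The mycorrhiza reads used for pine were those that had not mapped to the fungus, so any pine reads that mapped to it were not counted. Over the mycorrhiza libraries the 5 lower contigs were 126220 reads below the pine root level. The near-identical fungal families higher than in both other materials were 363110 reads above the scaled mycelia level. Whether reads lost in this way account for the 5 lower contigs was not tested. Without pine root column C edgeR called 6 higher and 12 lower. It called 0 higher and 1 lower without pine root column A, mycorrhiza column A or mycorrhiza column B, 2 and 1 without pine root column B, and 2 and 8 without mycorrhiza column C. With replicate number as a block, on reads recovered from the RPKM, none of the 7 passed, at edgeR adjusted p of 0.119 to 0.253.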

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

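The alternatives on centred or rescaled RPKM and on recovered reads, and the pine runs on recovered reads or without contigs under 3 reads in pine root, were chosen only after the data were seen, and the others were planned. For mycorrhiza against mycelia, 1407 genes higher and 4992 lower became 2952 and 2249 with centred RPKM, 2556 and 2465 with TMM, 2582 and 2439 with DESeq2 size factors in edgeR, 2938 and 2427 with DESeq2, and 854 and 2866 with thinned reads. A log2 change of at least 1 left 932 higher. Against fruiting bodies, 1847 and 4319 became 2876 and 2616 with centred RPKM, 2935 and 2652 with DESeq2, and 1193 and 2620 with thinned reads. The lower count was 2813 with TMM and 2673 with DESeq2 size factors. For fruiting bodies against mycelia, 2185 higher became 3377 with TMM, 3439 with DESeq2 and 1456 with thinned reads, and 3322 lower became 1954 with thinned reads.

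Genes higher and lower in mycorrhiza than in both other materials, 693 and 2797, became 1521 and 1081 with centred RPKM, 1177 and 1282 with TMM, 1240 and 1222 with DESeq2 size factors, 1425 and 1221 with DESeq2, 359 and 1383 with thinned reads, and 1107 and 1601 without the near-identical families. A log2 change of at least 1 left 1617 lower. Centring shifts all genes of a library by the same amount, which moves the median gene toward 0 and can change the spread between libraries. Thinned reads leave fewer reads to test, and a minimum change leaves fewer genes by construction. The TMM and DESeq2 alternatives changed the test as well as the scaling, and for these and the other differences the cause was not tested.

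The fungal counts stayed within 1.5 times with no filter, a pseudocount of 0.1, replicate number as a block and only the compared libraries. Without single libraries they ran over 1119 to 1586 higher and 3981 to 5190 lower against mycelia, 1500 to 1990 and 3428 to 4528 against fruiting bodies, and 1708 to 2002 and 2491 to 2862 for fruiting bodies against mycelia. Replicate numbers did not pair the samples, since correlations of deviations between libraries with the same number ran from -0.116 to 0.165. With an estimated correlation the set calls had adjusted p of 0.328 for hydrophobins, 0.322 for plant cell wall degrading enzymes, redox genes and transcription factors, 0.390 for ribosomal proteins and 0.383 for sugar transporters between mycorrhiza and mycelia, and 0.520 for ribosomal proteins between fruiting bodies and mycelia. The estimated correlations were 0.0215 for transcription factors to 0.182 for ribosomal proteins, but 0.00314 for plant cell wall degrading enzymes, under the preset 0.01. The unadjusted camera p of these enzymes still rose from 0.00258 to 0.0154, so a higher correlation does not account for their loss. For the other lists the cause was not tested. With replicate number as a block none of the set calls changed. Of 439 calls of named genes, 429 held with centred RPKM, 9 lost the threshold and 1 reversed, gene 512549 between mycorrhiza and mycelia, at 0.13. With DESeq2 size factors in edgeR 430 held.

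For pine, 2 contigs higher and 5 lower became 360 and 433 with DESeq2, 6 and 9 with thinned counts, and 0 and 0 with replicate number as a block on recovered reads. Without single libraries they ran from 0 to 6 higher and from 1 to 12 lower. The block costs degrees of freedom among 6 libraries; for the others the cause was not tested, although planted changes gave 119 unchanged contigs among the DESeq2 calls and 11 with edgeR. DESeq2 size factors in edgeR, recovered reads, a log2 change of at least 1 and leaving out contigs under 3 reads in pine root gave 2 and 5, and no filter 2 and 4. The planned run without fungal-type contigs was not run, since no descriptions were used, and a pseudocount applied to no pine value. Depth limits the fungal values of mycorrhiza, where 1 read stood for up to 2.70 RPKM in a gene of 1 kilobase.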

Other observations

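The tests of explanations for the patterns described here, and the counts over other splits of the libraries, were chosen only after the results were seen, while the gene lists were fixed beforehand except that of near-identical families. Of the lists that passed in no comparison, mating, meiosis and fruiting genes gave 12 higher and 67 lower of 114 between mycorrhiza and mycelia, and 18 and 37 after centring on the median gene. Proteases gave 7 higher and 42 lower of 79, 7 and 43 adjusted over the list alone, but 16 and 11 after centring and 13 and 17 with TMM. Lectins gave 9 and 28 of 68, and 19 and 13 after centring, and lectin gene 1457815 fell 11.3-fold from 256 ± 37.0 to 22.7 (SD, n = 3). Phosphate, sulfate and metal transporters gave 13 and 15 of 45, and the trehalose, glycogen and polyol list 6 and 7 of 30, which became 19 and 5 and 12 and 3 after centring. Genes of fungal cell wall synthesis and turnover gave 12 higher and 51 lower of 98, and 23 and 32 after centring. Isocitrate lyase 1455722, of the glyoxylate cycle, was at 440 ± 311 in fruiting bodies, 8.04 ± 5.89 in mycorrhiza and 3.24 ± 0.66 in mycelia. Its mean was 277 without fruiting body 1 and 4.65 without mycorrhiza 1.

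The 26 near-identical family members higher in mycorrhiza than in both other materials were of ubiquitin, actin, histone and similar families, taken to be near-identical in plants and fungi from their descriptions alone. Pine reads aligned to fungal gene models stay a candidate explanation: the median log2 ratio of their reads in mycorrhiza 3 over mycorrhiza 1 was -0.17 (interval -0.36 to -0.05, all 26 genes), nearer to pine reads at -0.39 than to the other tested fungal genes at 0.28 (interval 0.27 to 0.30). For the 667 other genes as a set pine reads were argued against, since their median ratio was 0.34 (interval 0.29 to 0.40). It was 0.34 and 0.32 in the 79.6% and 70.0% with at least 10 and 20 reads in both libraries. Single genes or a minority among them stay open, since 23.4% were nearer to the pine ratio, against 24.7% of the other tested fungal genes. These intervals come from a bootstrap over genes of a ratio between 2 libraries, so they do not measure the spread between libraries. Higher expression of these families by the fungus in mycorrhiza was not tested.

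More genes were lower than higher in mycorrhiza than in mycelia, at a median log2 change of -0.60. The low depth of the mycorrhiza libraries was argued against, because 23.0% of the calls were higher after thinning to the smallest library and unchanged groups simulated at these depths had at most 13 lower calls. A few gene families taking a large share of the reads may account for part of the shift, which was -0.27 after the near-identical families were left out and RPKM was rescaled. These families were chosen after their values were seen, and leaving out their large share raises all other mycorrhiza genes by construction. The value therefore gives the size of that effect and is no independent test. The rest of the shift stays open between the materials, their RNA extraction methods, and growth at 23 °C in the light or 25 °C in the dark, which cannot be told apart here. A lower transcript level of most genes in the fungus on roots was not tested.

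For 7830 genes at least 10 mycorrhiza reads were due at their lowest scaled value among the mycelia and fruiting body libraries. Of these, 13 genes were at 0 in every mycorrhiza library. Counting noise alone at this depth was argued against, since 20 draws from the mycelia levels gave at most 0 such genes, as the minimum of 10 reads nearly ensures. The draws left out the wider spread between the mycorrhiza libraries, whose pairs had a chi-square per gene of 4.21 to 5.84. Low depth together with that spread therefore stays open for these 13 genes. A fungal genotype that differs between mycorrhiza and mycelia is a candidate explanation: 2 descriptions were shared between these genes and the 20 genes at 0 in mycelia but read in every other library. Of 10000 random draws none gave as many. With the observed sets counted in, this is a share of 0.0001, the smallest that so many draws can give. RNA polymerase subunit gene 1250091 had 0 reads in mycorrhiza and 2637, 3383 and 3165 in mycelia, while 1250276, the only other gene with that description, had 18, 10 and 28 in mycorrhiza and 0 in mycelia; the other shared description was a general kinase term carried by 53 genes. Both materials were labelled with strain IS01, read sequences were not used here, and regulation of these genes was not tested.

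For the comparisons of 3 with 3 libraries the 10 splits are too few for a share under 0.05. The real splits gave 6399 calls for mycorrhiza against mycelia, 6166 against fruiting bodies and 5507 for fruiting bodies against mycelia, each the only 1 of its 10 splits with as many, and the highest other split gave 0 in each. For genes called the same way in both mycorrhiza comparisons, 1 of 100 splits, the real one with 3490, gave as many, and the highest other gave 1471. The other splits mix materials within a group, so this share shows only that the calls follow the grouping by material. It does not exclude chance differences between single cultures or collections. For pine the real split gave 7 contigs, 3 of 10 splits gave as many, and the highest other gave 49. That split set pine root columns A and B and mycorrhiza column B, the 3 libraries with the lowest totals, against pine root column C and mycorrhiza columns A and C. Such a count points to a structure of the samples, and as this split follows the library totals, depth was not separated from other differences between the libraries.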
